A study of Canis lupus familiaris with 4 samples.

How the data were processed

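Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open DNA, in 4 libraries of MDCKII, an epithelial line derived from canine kidney. Per the labels, 2 libraries (A and B) came from monolayers grown for 7 d to full maturity, and 2 (A and B) came from such monolayers that were detached and reseeded for 2 h. Per the labels' protocols, nuclei were transposed and the libraries amplified by PCR and purified on columns and beads.

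The authors' deposited table holds raw counts for 59081 peaks in each of the 4 libraries, not normalized and of a different total in each library. Per the submitters' processing notes, the tools were Bowtie2 and MACS2 and the genome build was CanFam3.1. Their versions and settings, the treatment of duplicate and multiply aligned reads, the Tn5 offset, and whether reads, fragments or insertions were counted are not given in the sources used here. The rule by which peaks entered the table is not given there either. Every peak was 501 bp wide. The table names chromosomes by sequence accession, which were read as chromosomes 1 to 38 and X, and positions are printed counting from 1. Duplicates and multiply aligned reads can change counts in repeated sequence, and a peak set picked for detection in some of the libraries holds few peaks that are weak in both groups.

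Total counts in peaks were 8759513 and 6253706 in mature libraries A and B and 16906566 and 24015663 in reseeded libraries A and B. A count of 3 was taken as the floor, which equals 0.342, 0.48, 0.177 and 0.125 CPM (counts scaled to a common library total) in that order. The labels name no molecular identifiers, so PCR copies may be counted, and floors and counting intervals cover counting error only.

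The counts as deposited by the authors were analysed in R 4.3.3 with edgeR 4.0.16. Peaks passing filterByExpr (59076 of 59081) were scaled with trimmed-mean factors (TMM) and tested with edgeR's quasi-likelihood test, reseeded against mature, with no block. Adjusted p-values are Benjamini-Hochberg values over all tested peaks, and a peak was called at an adjusted p under 0.05. Log2 folds are reseeded over mature, CPM values are TMM-scaled, and the SE of a log2 fold was taken from the fold and its F statistic. Because most peaks were called, calls were also divided at a fitted fold of 2 and of 4, a division added after the data were seen. Counts were summed in windows of 1 Mb holding at least 5 peaks and tested in the same way. For the named peaks, counting intervals on the ratio of pooled counts are exact Clopper-Pearson intervals at 95%. On simulated counts for 59081 peaks drawn at the fitted dispersion, the edgeR test recovered 70 of 100 peaks changed by 1.5-fold and 95 of 100 changed by 2-fold, with 13 false calls. For simulated 1 Mb windows it recovered 20 of 20 changed by 1.3-fold, with 1 false call. Only 200 peaks were changed, and all peaks and windows shared the common dispersion fitted to peaks. The simulations therefore do not show the error rate where most peaks differ or the groups vary unequally.

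The named peaks were fixed by rule: the 10 highest and 10 lowest log2 folds among called peaks with a mean count of at least 50 and no overlap between the groups in CPM, and the 3 highest and 3 lowest called windows of 1 Mb. With 2 libraries in each group, 33.3% of peaks have groups that do not overlap by chance. Relations to peak density, chromosomes, chromosome ends and neighbouring peaks, and windows in which most peaks moved one way, were chosen after the data were seen and examined with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Shuffles moved folds among the peaks of a chromosome.

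Alternatives in place of TMM were DESeq2 size factors, upper-quartile factors, library size alone and loess offsets trended on each peak's mean log2 CPM. Others were no count filter, a filter of at least 30 counts in 2 libraries and the Wald test of DESeq2 1.42.0. Further ones were voom in limma 3.58.1, an adjusted p under 0.01 and a test against a fold of 1.5 (glmTreat). Last came a replicate block by library letter, numbered chromosomes alone, windows of 500 kb and 5 Mb, and each library left out in turn. With 1 library left in a group, that library was assumed to vary as the pair of the other group does. Thinning all libraries to the shallowest total, and deciles of mean CPM with equal weight for the groups, were added after the data were seen.

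The gene annotation used for this organism describes another assembly (UU_Cfam_GSD_1.0), so peaks were not placed on genes. The promoter and distal classes, 20 gene lists, 27 motifs and GC corrections that had been planned were therefore not run. Peak width was the same throughout and gave no relation.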

Results

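Accessible chromatin of MDCKII cells, a canine kidney line that forms polarised epithelial monolayers, was compared between mature monolayers grown for 7 d (n = 2 libraries, A and B) and cells of such monolayers 2 h after detachment and reseeding (n = 2 libraries, A and B). The series concerns folds of the nuclear envelope and the arrangement of chromatin, and the comparison asks which regions differ in accessibility between the mature and the freshly reseeded state. Counts in 59081 peaks of 501 bp totalled 8759513 and 6253706 in mature libraries A and B and 16906566 and 24015663 in reseeded libraries A and B. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. A leading code in the sample names differs between the groups and is shared within each, so a batch that followed it cannot be told apart from reseeding.

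Libraries of a group were close to each other and far from the other group. Across peaks, which are not independent replicates, Pearson's r of log2(CPM + 0.5) was 0.975 between the mature libraries and 0.991 between the reseeded libraries, against 0.38 to 0.387 between groups. Spearman's rho was 0.977 and 0.99 within groups and 0.43 to 0.437 between them. The chi-square per degree of freedom of the counts was 1.74 for the mature pair, 1.10 for the reseeded pair and 39.4 to 56.5 between groups. The reseeded pair differed by slightly more than counting noise (chi-square p = 4.17e-59 on 58986 degrees of freedom), so its libraries were not treated as a single library listed again. That test covers counting error only and does not show separate cultures. Counts were more concentrated in mature cells, where the strongest 10% of each library's own peaks held 33.3% and 32.1% of its counts, against 28.0% in each reseeded library.

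Accessibility differed at most peaks 2 h after reseeding, in both directions. At least 2-fold higher accessibility was found at 15871 peaks (26.9% of 59076 tested) and at least 2-fold lower accessibility at 8886 peaks (15.0%). At least 4-fold differences comprised 5982 higher peaks, with median CPM of 2.54 in mature and 15.0 in reseeded cells, and 3566 lower peaks, with median CPM of 16.2 in mature and 2.13 in reseeded cells. A further 24931 peaks (42.2%) were called with folds under 2. By edgeR's quasi-likelihood test at an adjusted p under 0.05, 49688 peaks (84.1%) were called in all, 24966 higher and 24722 lower, and 9388 were not. After TMM scaling the median log2 fold was -0.0086. Folds are relative to the other peaks, so a rise or fall shared by all peaks would not show. The common dispersion was 0.00109, a coefficient of variation of 3.3% between libraries of a group beyond counting error. A test against a fold of 1.5 called 30511 peaks, 18162 higher and 12349 lower. The excess of gains held under every scaling tried but loess offsets. At least 2-fold, 16360 peaks were higher and 8453 lower by library size alone, and 16355 and 8455 by upper-quartile factors. DESeq2 size factors gave 15893 and 8858. Under loess offsets trended on mean log2 CPM, 9809 peaks were at least 2-fold higher and 9709 lower, and 2485 were at least 4-fold higher and 4516 lower. As mean log2 CPM is low wherever the fold is large, these offsets can take up part of the folds themselves. Whether the deeper reseeded libraries brought more of their own peaks into the table, and so more gains, is not known.

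The peak set held few peaks that were weak in both groups. Mean CPM was under 5 at 11618 tested peaks in mature cells and at 4785 in reseeded cells, and at 28 peaks in both. With both groups weighted equally, peaks at least 2-fold higher made up 66.5% of the lowest decile of mean CPM and 5.8% of the highest, and peaks at least 2-fold lower 12.0% and 8.9%, with their largest share, 22.5%, in decile 3. With log2 CPM averaged instead, which is low wherever the fold is large, higher and lower peaks made up 69.1% and 24.3% of the lowest decile. For each this was the largest share of any decile. As peaks weak in both groups were nearly absent, a low mean here goes with a difference between the groups. Mature library B exceeded mature library A at peaks that were higher after reseeding, with a median log2 ratio of 0.30 at the peaks at least 4-fold higher and -0.01 at peaks that were not called. Without mature library A 4849 peaks were at least 4-fold higher, and without mature library B 7147.

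**Figure D1:**
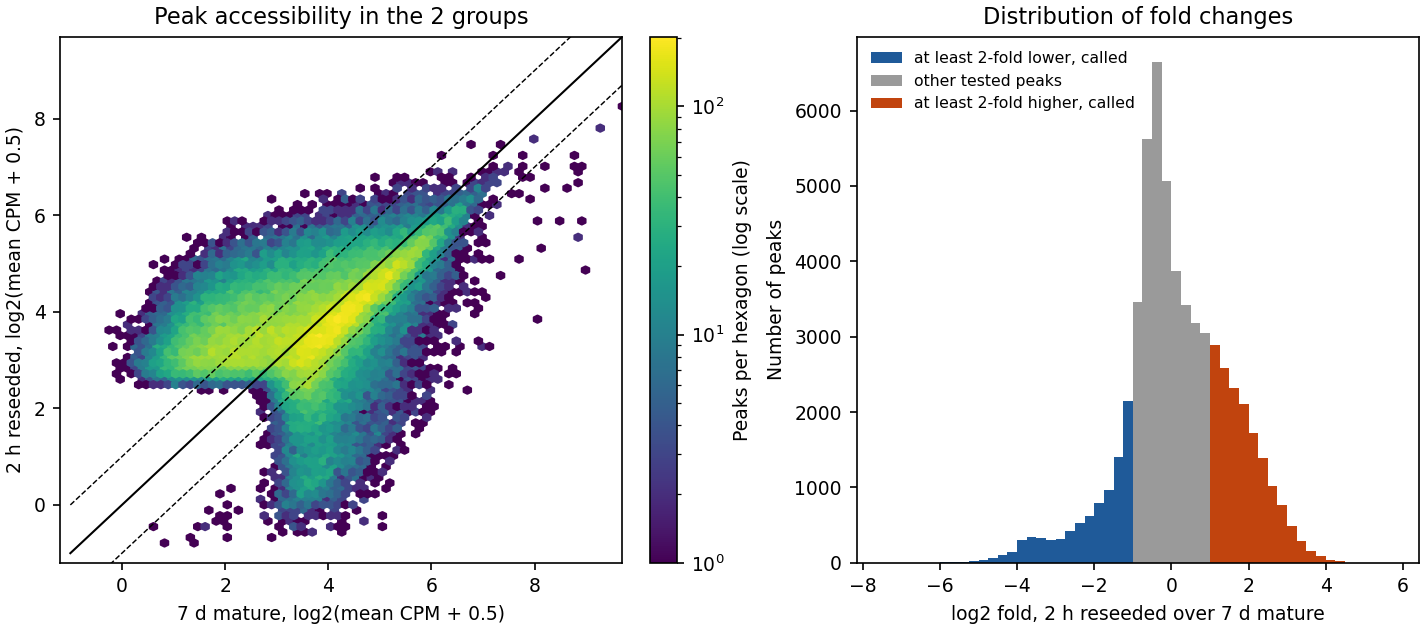
Left, log2(mean CPM + 0.5) of each tested peak in 7 d mature cells (x axis) and 2 h reseeded cells (y axis), with hexagons coloured by number of peaks on a log scale, a solid line of equality and dashed lines at 2-fold. Right, number of peaks by log2 fold of reseeded over mature, with the 8886 called peaks at least 2-fold lower in blue, the 15871 at least 2-fold higher in orange and all other tested peaks in grey.

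Among the peaks with the largest gains, accessibility went from near the counting floor in mature cells to clear peaks in reseeded cells. The peak on chromosome 24 from 11228768 to 11229268 (CanFam3.1) rose from 1.01 ± 0.0509 CPM to 32.4 ± 0.887 CPM (mean ± SD, n = 2 per group), a log2 fold of 4.99 (SE 0.19, adjusted p = 2.18e-21). The peak on chromosome 3 from 49247303 to 49247803 rose from 1.80 ± 0.898 to 44.8 ± 1.39 CPM, a log2 fold of 4.72 (SE 0.17), and that on chromosome 11 from 23827999 to 23828499 rose from 1.19 ± 0.375 to 33.0 ± 2.46 CPM, a log2 fold of 4.84 (SE 0.20). The highest log2 fold, 5.41 (SE 0.36, adjusted p = 1.76e-15), was at chromosome 11 from 61819399 to 61819899, where 4 mature counts in all faced 493 reseeded counts. Its pooled ratio was 45.2 (95% counting interval 17.5 to 167). The other 6 peaks, with log2 folds of 4.48 to 4.99, lay on chromosome 1 from 32527414 to 32527914 and from 61232839 to 61233339, on chromosome 12 from 24655300 to 24655800 and from 58623037 to 58623537, on chromosome 4 from 69967008 to 69967508 and on chromosome 33 from 28296239 to 28296739. Within 50 kb of these 10 peaks lay 23 other tested peaks, of which 17 were at least 2-fold higher and 0 at least 2-fold lower. Leaving out a mature library moved the fold by over 1.5 times at 2 of the 10: it was 24.1 without mature A and 95.5 without mature B at the chromosome 11 peak from 61819399, and 14.2 and 93.2 at the chromosome 12 peak from 58623037. Loess offsets gave log2 folds of 1.61 to 4.56 for the 10 peaks.

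Among the peaks with the largest losses, 3 lay within 1.9 kb on chromosome 27 and 2 within 7.8 kb on chromosome 25. A peak on chromosome 27 from 2947116 to 2947616 fell from 33.7 ± 0.711 CPM in mature cells to 0.219 ± 0.020 CPM in reseeded cells, a log2 fold of -7.22 (SE 0.21, adjusted p = 4.27e-24), or 149-fold (95% counting interval of the pooled counts 78.7 to 331). Its neighbours from 2947988 to 2948488 and from 2946587 to 2947087 fell with log2 folds of -6.68 (SE 0.34) and -6.39 (SE 0.21). On chromosome 25, the peak from 29995687 to 29996187 fell from 20.3 ± 1.5 to 0.211 ± 0.0502 CPM (log2 fold -6.49, SE 0.29), and the peak from 30002982 to 30003482 fell with a log2 fold of -5.96 (SE 0.34). Chromosome 4 from 10773814 to 10774314, chromosome 2 from 59601815 to 59602315 and from 43646966 to 43647466, chromosome 27 from 2188096 to 2188596 and chromosome 6 from 41910283 to 41910783 held the other 5, with log2 folds of -6.31 to -5.77. Around the 10 lower peaks, 128 other tested peaks lay within 50 kb, with peaks near several of them counted each time, and 57 were at least 2-fold lower and 5 at least 2-fold higher. Loess offsets gave these peaks log2 folds of -9.64 to -8.07.

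**Figure D2:**
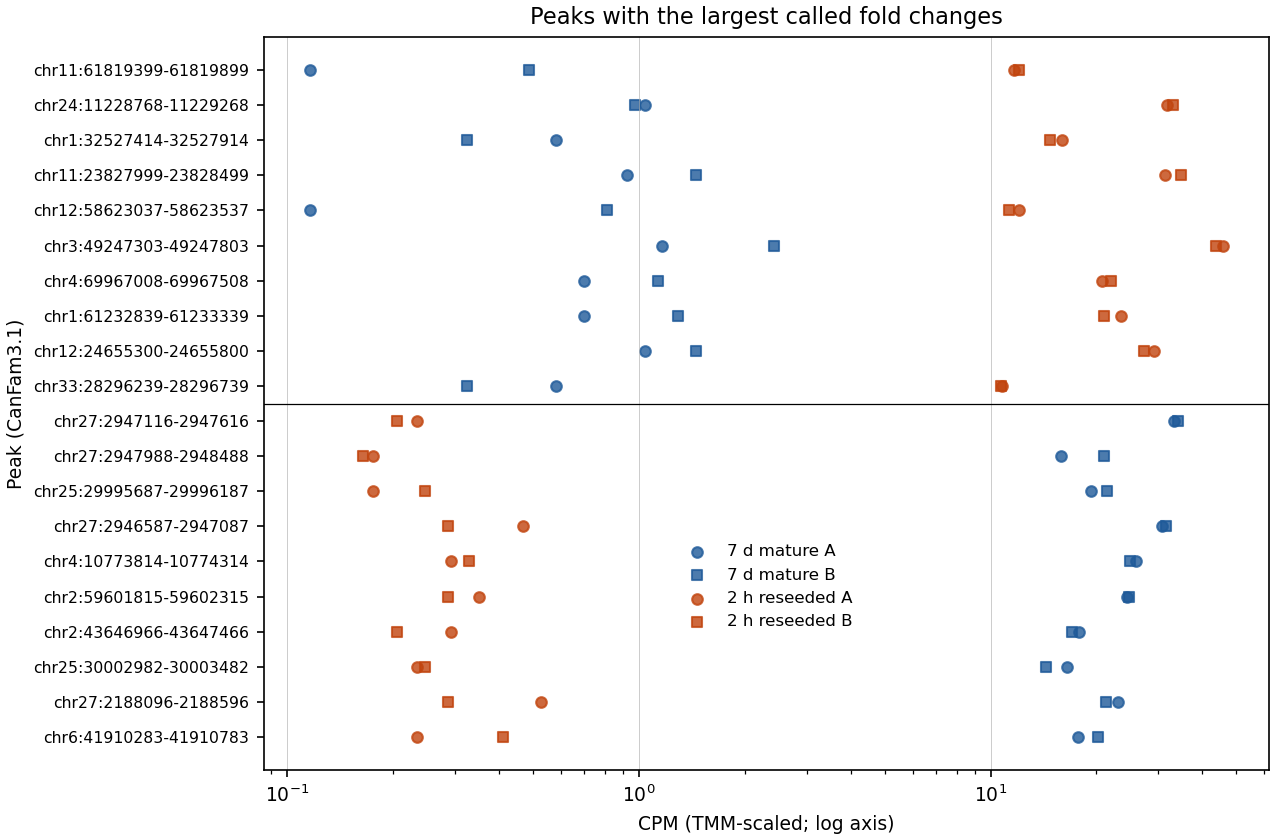
CPM (TMM-scaled, log axis) of the 10 peaks with the highest and the 10 with the lowest called log2 fold, named by position in CanFam3.1, with 1 point per library (blue, 7 d mature; orange, 2 h reseeded; circles, A; squares, B). The groups do not overlap at any of these peaks, which the naming rule required, and the chromosome 27 peak at 2947116 lies near 33.7 CPM in mature and near 0.219 CPM in reseeded cells.

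Summed over 1 Mb, accessibility rose most in windows on chromosomes 29, 24 and 22 and fell most in windows on chromosomes X, 13 and 8. The window of chromosome 29 from 20000001 to 21000000 rose from 30.3 ± 5.31 to 137.9 ± 4.2 CPM (n = 2 per group), a log2 fold of 2.22 (SE 0.09, adjusted p = 9.03e-07), with 8 of its 9 peaks at least 2-fold higher. Windows of chromosome 24 from 14000001 to 15000000 (7 of 7 peaks) and chromosome 22 from 53000001 to 54000000 (6 of 6 peaks) rose with log2 folds of 2.20 (SE 0.07) and 2.13 (SE 0.06). The window of chromosome X from 49000001 to 50000000 fell from 191.6 ± 66.5 to 24.5 ± 1.43 CPM, a log2 fold of -2.95 (SE 0.23, adjusted p = 1.67e-05), with 20 of 21 peaks at least 2-fold lower, all within 50.4 kb. Windows of chromosome 13 from 40000001 to 41000000 (17 of 18 peaks) and chromosome 8 from 73000001 to 74000000 (10 of 11 peaks) fell with log2 folds of -2.87 (SE 0.22) and -2.73 (SE 0.23). In these lost windows the mature libraries themselves differed: on chromosome X mature A had 144.5 CPM and mature B 238.6 CPM. By edgeR's quasi-likelihood test, 1566 of 1803 windows (86.9%) were called, 798 higher and 768 lower, of which 45 and 24 by at least 2-fold. The 2-fold counts were 64 and 15 when scaled by library size alone and 29 and 22 under loess offsets. Scaling by library size alone gave 1009 higher and 537 lower windows, with 65.3% of calls higher in place of 51%, and moved the median log2 fold of all windows from 0.02 to 0.13.

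**Figure D3:**
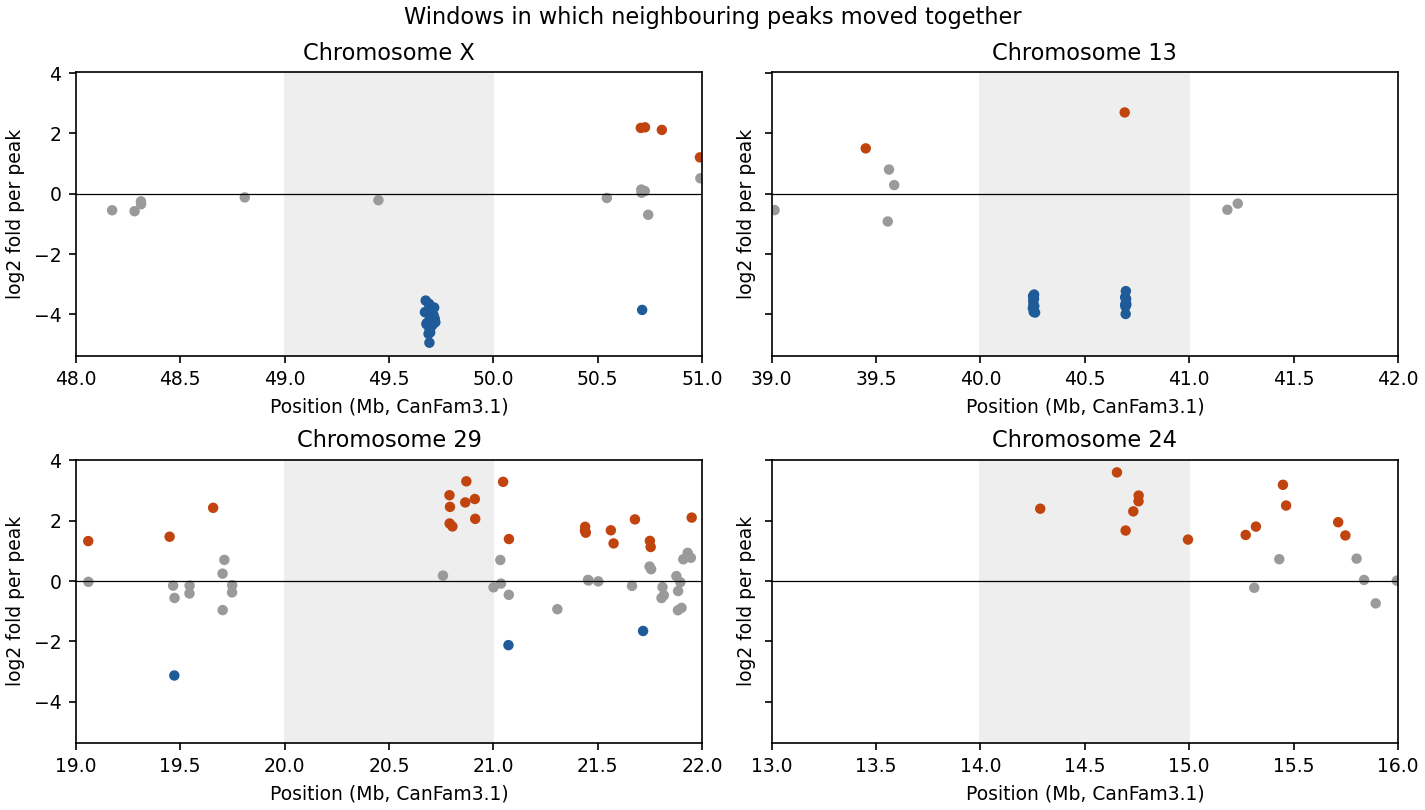
Log2 fold of each tested peak against its position (Mb, CanFam3.1) in and around 4 of the named windows of 1 Mb, shaded grey, with called peaks at least 2-fold higher in orange, called peaks at least 2-fold lower in blue and other peaks in grey. On chromosome X the 20 lower peaks lie within 50.4 kb, and on chromosome 29 the 8 higher peaks spread over 123.9 kb.

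Peaks within 1 kb of each other mostly differed alike, and more distant neighbours only weakly so, as examined after the data were seen. Distances were taken between the midpoints of peaks 501 bp wide, so the closest pairs may cover parts of a single accessible region. The correlation of log2 folds across pairs of adjacent peaks was 0.617 up to 1 kb apart (6813 pairs, 72.8% of one sign), 0.33 from 1 to 5 kb (14837 pairs, 60.3%), 0.195 from 5 to 20 kb (18313 pairs, 57.6%) and 0.128 from 20 to 100 kb (15157 pairs, 55.4%). Folds shuffled within chromosomes gave at most 0.054, 0.04, 0.042 and 0.045 in 200 shuffles. In 12 windows of 1 Mb at least 80% of peaks were at least 2-fold higher and in 5 windows at least 80% were at least 2-fold lower. The means in 1000 shuffles were 2.80 and 0.222 (permutation p = 0.001 for each, the smallest these shuffles can give). The shuffles did not keep local peak density, and gains were most frequent where peaks were sparse. For the 12 windows they cannot tell neighbours gaining together from sparse regions gaining more. The shuffles also break the correlation of close neighbours, so for the 5 windows they do not show clustering beyond it.

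Gains were most frequent where peaks were sparse and losses of at least 2-fold where peaks were dense, a relation examined after the data were seen. In the decile of peaks with the fewest others within 500 kb either side (median 12 peaks), 37.0% were at least 2-fold higher and 12.3% at least 2-fold lower. In the densest decile (median 104 peaks) these shares were 12.0% and 19.5%. At least 4-fold gains went from 17.7% in the sparsest to 2.9% in the densest decile, whereas at least 4-fold losses differed little, at 6.5% and 7.1%. Chromosome 29, with 12.8 peaks per Mb, had a median log2 fold of 0.76 and chromosome 32, with 14.7 peaks per Mb, 0.51, whereas chromosome 9, with 58.3 peaks per Mb, had -0.28 and chromosome 20, with 44.5 peaks per Mb, -0.31. Chromosome X departed from this order, with 11.4 peaks per Mb and a median log2 fold of -0.26. Across 39 chromosomes, the median log2 fold was related to peaks per Mb with Pearson's r of -0.656 and Spearman's rho of -0.678 (2-sided permutation p = 1e-05 for each, the smallest that 100000 resamples can give, and 1e-05 after Benjamini-Hochberg adjustment over 4 tests). Without the 2 chromosomes farthest from the median density, r was -0.586 and rho -0.623, and over the 38 numbered chromosomes r was -0.762 and rho -0.79. Mature A against reseeded A alone gave a rho of -0.68 and mature B against reseeded B -0.691. Density was counted on the same peak set as the folds, and all chromosomes were measured in the same 4 libraries, so they are not independent samples. The relation of fold to mean level depended on how the level was averaged. The mean count of the fit is weighted to the reseeded libraries, which held 73.2% of the counts, so lost peaks fall to its low end, and it gave a rho of -0.002 across peaks and of 0.35 under loess offsets. Mean CPM with equal weight for the groups gave -0.252, and mean log2 CPM -0.262.

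**Figure D4:**
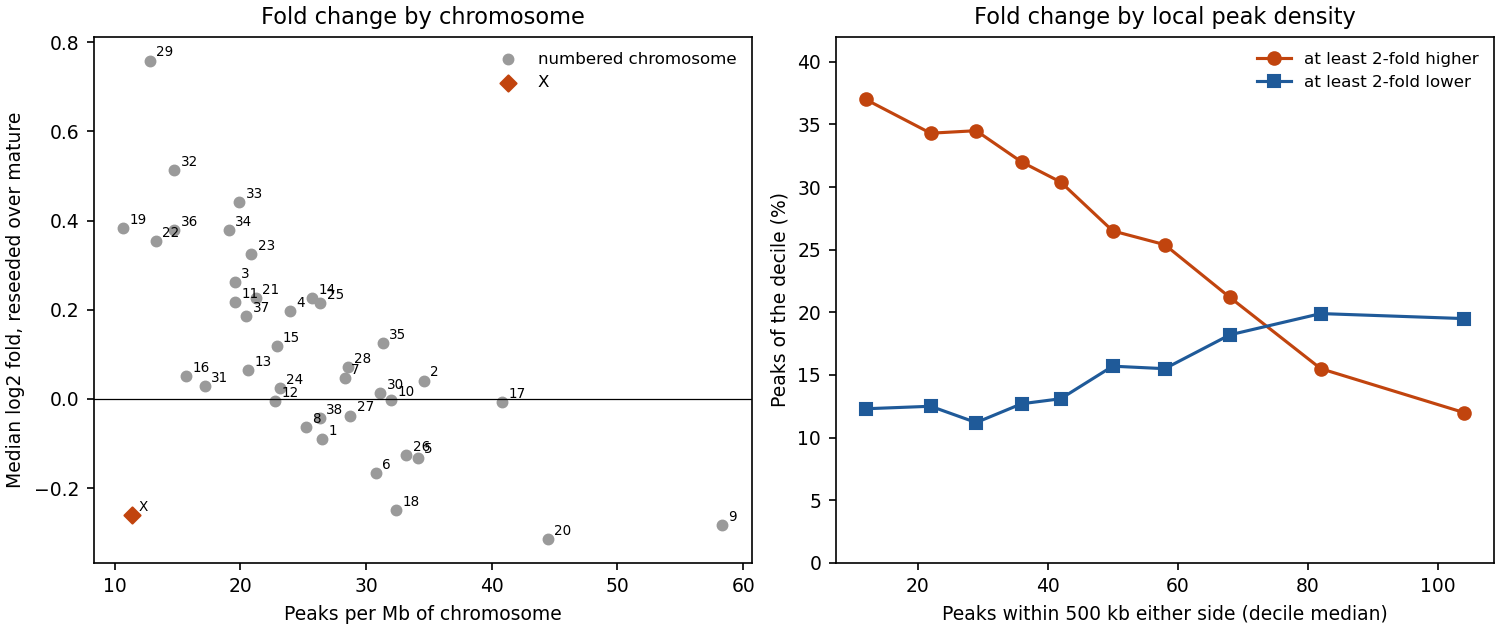
Left, median log2 fold of reseeded over mature for each chromosome against its peaks per Mb, with chromosome X as an orange diamond and numbers naming the others. Right, percent of peaks at least 2-fold higher (orange circles) and at least 2-fold lower (blue squares) by decile of the number of peaks within 500 kb either side, from 37.0% and 12.3% in the sparsest to 12.0% and 19.5% in the densest decile.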

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

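Thinning to the shallowest library, equal group weights, the settings at a 2-fold or 4-fold bound, the chromosome relation and the loess, upper-quartile, DESeq2 and voom counts of called windows were chosen after the results were seen; the other settings were fixed before the data were examined. Of 142 alternatives for the main counts and relations, 130 kept their direction and stayed within 1.5 times the count or on the same side of the threshold. Against a fold of 1.5, 30511 peaks were called and 12349 were lower, because small folds no longer pass. Loess offsets left 9809 peaks at least 2-fold higher against 9709 lower, and 2485 at least 4-fold higher against 4516 lower. The excess of 4-fold gains thus turned to one of losses. These offsets followed mean log2 CPM, which itself moves with the fold: with equal group weights its lowest decile had a median log2 fold of 1.64. Part of the turn can come from that trend, and its share was not tested. Windows of 5 Mb gave 412 calls (213 higher, 199 lower) and windows of 500 kb gave 2477 (1280 higher, 1197 lower), as fewer or more windows were tested. The relation of fold to mean count was 0.35 under loess offsets, -0.023 to 0.026 with a library left out and -0.252 with the groups weighted equally, so it was not stable. Chromosome rho ranged from -0.557 (loess offsets) to -0.79 (numbered chromosomes), and was -0.793 for numbered chromosomes without the windows lost together. All 26 named peaks and windows kept direction and threshold under 286 alternatives, with adjusted p of at most 0.0018. With a library left out, 44804 to 49454 peaks were called. The replicate block called 48979 peaks and 1527 windows and ended no call of a named peak or window; the letters did not show pairing, as the A minus B differences of the groups correlated at 0.0315 across peaks. Depth limits small folds: mature totals were lowest, and thinning called 46356 peaks. GC offsets, alone or with the block, and the promoter, gene list and motif analyses were not run, because no genome or annotation of the build was used here.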

Other observations

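The tests of runs, chromosome ends, chromosome X, uniform background, library code, deletion, repeated sequence and background-like reads were chosen after the result was seen.

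Losses of at least 4-fold came in unbroken runs. In 40 places on 16 chromosomes, at least 5 neighbouring tested peaks, no more than 10 kb apart, were all at least 4-fold lower after reseeding, and these held 338 peaks (9.5% of those at least 4-fold lower). Shuffled folds gave at most 1 such run in 200 shuffles. The shuffles separate close neighbours, whose folds were correlated, so they cannot show runs beyond that correlation. The run with the most peaks was on chromosome 27 from 13140350 to 13174553, with 28 peaks and a median CPM of 27.3 in mature and 1.82 in reseeded cells, followed by chromosome 7 from 80946834 to 80963745 (21 peaks), chromosome 6 from 43061656 to 43081016 (20 peaks) and chromosome X from 49672154 to 49722525 (20 peaks). In these runs the mature libraries disagreed, with median log2 ratios of B to A of 0.66, 0.67, 0.63 and 0.71. They belong to 26 runs, with 245 peaks, in which this ratio was above 0.3. No run of this kind (0) was higher by edgeR calls, nor by the folds alone of DESeq2 (0), voom (0) or loess offsets (0), which rest on the same counts. In shuffles such higher runs numbered 0.1 on average and at most 2, so their absence does not differ from the shuffles. At a 2-fold bound, 22 runs of at least 5 peaks were higher (at most 19 in shuffles) and 72 lower (at most 3). Shorter runs, of at least 3 peaks, included gains too. At 4-fold 46 were higher (at most 30 in shuffles) and 111 lower (at most 11), and at 2-fold 431 (at most 328) and 309 (at most 82). In 14 of the 40 runs, with 93 peaks, mature libraries A and B were closer, with median log2 ratios of B to A from -0.27 to 0.28. Among these were chromosome 27 from 2946587 to 2954727 (median log2 fold -5.71), chromosome 1 from 110084747 to 110089178 (-5.35) and chromosome 30 from 6772909 to 6787966 (12 peaks, -4.54). Their ratios of B to A were 0.28, -0.12 and -0.27, so the chromosome 27 run lay just under the bound of 0.3.

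Chromosome ends and chromosome X carried more losses. In the last 1 Mb before the final peak of each chromosome, 28.5% of 1102 peaks were at least 2-fold lower, against 14.8% elsewhere (odds ratio 2.3, Fisher's exact test, 2-sided, adjusted p = 8.89e-30 over 8 tests), with a higher share on 32 of 39 chromosomes. In the first 1 Mb the share was 24.2% of 1206 peaks against 14.9% (odds ratio 1.83, Fisher's exact test, adjusted p = 6.41e-17), higher on 28 of 39 chromosomes. On chromosome X, 12.0% of 1409 peaks were at least 4-fold lower, against 5.9% on numbered chromosomes (odds ratio 2.18, Fisher's exact test, adjusted p = 7.34e-17 over 4 tests), and 7.8% against 5.4% without the runs (odds ratio 1.47, exact p = 0.000341). Neighbouring peaks are not independent, so these p-values are too small.

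Most peaks were called changed. A difference in depth at the test is argued against as the whole cause. Of the peaks called at least 2-fold changed, 95.4% were so called again after all libraries were thinned to the shallowest. Thinning kept the same set of peaks, so it cannot show whether depth affected which peaks entered the table. A uniform background diluting the peaks of one group would, as the only difference, keep their order, but the highest rank correlation between a mature and a reseeded library was 0.437. This does not exclude such a background as part of the difference. Counts were less concentrated in the strongest peaks of the reseeded libraries, which partial dilution would also give. The library code in the sample names stays open, since 0 codes hold libraries of both groups, and it cannot be told apart from the reseeding itself, which stays open as the biological explanation the design names.

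Windows of peaks lost together may have a technical source. Complete deletion in the reseeded cells was weighed at the 69 peaks at least 2-fold lower in the 5 lost windows. Their median was 18 counts per peak in the lower of the reseeded libraries, above the bound of 3 set for deletion. Over all peaks of a window the medians in that library ran from 8 in the chromosome X window from 49000001 to 402 in the chromosome 1 window from 60000001. These counts argue against complete deletion only if few reads were misplaced, as the treatment of multiply aligned reads is not given. A loss of some copies was not tested. Background-like reads in the mature libraries stay open. At those 69 peaks mature B exceeded mature A by a median log2 of 0.649 (95% bootstrap interval 0.594 to 0.751), above the 0.301 at peaks at least 4-fold higher. The bootstrap drew single peaks, which are not independent within a window, so the interval is too narrow. The rule, written after the data were seen, accepted any ratio at or above that of the higher peaks. The ratio here exceeded theirs and did not match it, so it cannot show that these reads are such background. In 26 of the 40 runs the ratio of mature B to A was above 0.3. Reads of repeated sequence dropped in the reseeded libraries only stay open too. Reseeded CPM at the 67 peaks at least 4-fold lower in the lost windows was 0.564 of that at such peaks elsewhere (0.47 to 0.6, also drawn over peaks). Choosing windows for their loss lowers this ratio as well. A biological loss after reseeding was not tested apart from these, and the 14 runs in which the mature libraries were closer are where it could be followed first.

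The lower folds on peak-dense chromosomes were weighed against peak strength. Stronger peaks losing share everywhere is argued against by a median rank correlation of fold with density of -0.183 within deciles of mean count, negative in all 10 deciles (-0.263 to -0.125), and of -0.163 (-0.202 to -0.103) within deciles of mean CPM with equal weight for the groups and -0.145 (-0.212 to -0.097) within those of mean log2 CPM, tests added after the data were seen. Leaving out the windows lost together gave a rho of -0.793 across numbered chromosomes, but they held at most 1.38% of a numbered chromosome's peaks, too few to move a median, so this test decides nothing. GC content, which may follow peak density, was not tested, and an effect of reseeding on sparse and dense regions stays open as a hypothesis.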
